A study of Homo sapiens with 9 samples.

How the data were processed

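γH2AX, the histone H2AX phosphorylated around sites of DNA damage, was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in K562 cells, an established human myelogenous leukaemia line. The cells were wild type (WT) or knocked out (KO) for FANCL, a ubiquitin ligase of the Fanconi anaemia pathway of DNA crosslink repair. Per the labels' protocols, cells received 5 nM PMA, a phorbol ester that drives K562 cells to differentiate, or a mock treatment for 72 h. The 9 samples comprised 8 γH2AX libraries in 4 groups (WT mock, WT PMA, KO mock and KO PMA, 2 per group) and 1 input library from WT mock cells. Groups and replicate numbers were taken from the sample titles. The region lists hold no measurement of FANCL itself, so the genotype rests on the labels.

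Per the submitters' processing notes, CASAVA 1.4, BWA and HOMER were used and the genome build was hg19. Per the file headers, the authors called regions separately in each library with HOMER, against the WT mock input in every case. Windows of 500 bp passed at a tag threshold set from that library's depth (a probability of 0.001 in the caller's own model of tag numbers), at least 2-fold over input with a probability of 0.0001 in that model, and were joined into regions of variable length. Tags were limited to 1 per base pair. The deposited signal is the tag number of a region, normalised by the authors to 10 M tags of the library (M, mega), and the deposited input signal is the tag number in the same region of the input. In 5 libraries the authors also deposited the unscaled tag count of each region, and in the other 3 the tags scaled down to the depth of the input. The deposited fold of a region is the authors' ratio of its tags to input tags after scaling both libraries to one depth. The deposited score is HOMER's own region score, and each deposited p-value is HOMER's Poisson p for one region. Fold, score and p of a region are the authors' own values and were used to describe, rank or filter regions within a list. The KO and PMA libraries had no input of their own, so a region whose copy number differs from that of WT mock cells is not corrected for it.

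Depth per library came from the file headers and ran from 15.6 to 27.2 M tags. The input depth, 18.6 M tags, followed from the ratio of scaled to unscaled tags. Each library had its own tag threshold, from 5.89 tags per 10 M in the deepest to 7.69 in the shallowest, so a deeper library could call weaker windows. Shares of tags inside regions are given with exact Clopper-Pearson 95% intervals, which cover counting error only.

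Covered length was computed as the number of base pairs inside called regions, after merging, in whole libraries, in bins of 100 kb, on chromosomes 1 to 22 and X, and near chromosome ends. Bins covered in at least 2 libraries were tested with limma 3.58.1 in R 4.3.3, with a mean-variance trend, on log2(covered bp + 1000). All 8 libraries entered 1 fit with 4 groups, since 2 libraries per group are too few to estimate a spread alone. The threshold was a Benjamini-Hochberg adjusted p of 0.05, and all tests were two-sided. A log2 difference of a bin is on this scale, which understates changes of little-covered bins. Neighbouring bins are not independent of each other. Whole-library measures were compared on a log2 scale by exact permutation tests. With 2 libraries against 2 there are 6 labellings and the smallest p is 0.33. Shuffling within the other factor gives 36 labellings and a smallest p of 0.056. For the interaction, genotype was shuffled within each treatment. Its p therefore refers to no genotype effect of any kind, not to equal responses to PMA. Overlaps between lists were computed with bedtools 2.31.1, counting regions that shared at least 1 bp. A region was reproducible when called in both libraries of a group, and gained or lost when called in both libraries of one group and in neither library of the other. Other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

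The bins named in the text were fixed by a rule before the data were examined: in each comparison, the 5 bins with the largest change in each direction past the threshold, at most 1 per 10 Mb. For regions the rule took the 3 with the highest fold in the reproducible set of each group, at most 1 per Mb. Several results were added after seeing the data: limma on the log2 share of covered length per chromosome, the distance from chromosome ends, the regions of at least 5 kb, and the contigs outside the chromosomes. The chromosomes named, and the ends named one by one, were chosen after their values were seen. For ends, windows of 1 Mb were counted at 41 ends, leaving out the short arms of 5 acrocentric chromosomes. Together they made up 1.35% of the span of the chromosomes. The end of a long arm was the last position called in any library, not the chromosome length in the genome build. Windows there may therefore lie further inward. The share of called bins that lay in these windows was compared with 1000 circular shifts of the bin order, whose smallest two-sided p is 0.002.

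Tests of single genes, of the 17 gene lists fixed beforehand and of distance to transcription starts were not run, because no hg19 annotation was used here. Named positions are therefore given as hg19 coordinates with no statement of the gene they lie in.

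The bin fit was tested on simulated data. For KO against WT under mock treatment, 9635 simulated bins held 100 changes of each size; the fit recovered 8 at 4-fold, 47 at 8-fold and 70 at 16-fold, with 16 false calls. In a second simulation with broad changes in 9413 bins, false calls made up 8.92% of the calls for KO against WT under mock, 7.50% for KO against WT under PMA, 7.57% for PMA in WT and 10.6% for PMA in KO, above the nominal level. Bins changed at least 4-fold were recovered at 56.2%, 69.0%, 67.6% and 48.7% in the same order, none with the wrong sign. The fit thus misses many changes, and more of its calls are false than the threshold states. A lower bound on the residual spread, at the 20th percentile over bins, gave 3.47%, 3.38%, 3.84% and 3.10% false calls; it was added after these tests as an alternative, and the fit fixed beforehand was kept. The simulation itself was redesigned: earlier designs gave almost no calls at the smaller sizes, and the 16-fold size and the broad changes were added afterwards.

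Alternatives fixed before the data were examined were regions of at least 6-fold over input, the same number of regions from each library (11959, the highest scores), centring each library on its median, pseudocounts of 100 and 5000 bp, other filters, bins of 50 kb and 1 Mb, a larger required overlap, the replicate number as a block, and leaving out each library in turn. Added after seeing the data were one tag threshold for all libraries (7.69 tags per 10 M, applied to the best window of each region), regions of at least 1000 bp, the bound on the residual spread, other windows at chromosome ends, and covered length per chromosome in place of its share. One tag threshold does not remove depth in full. It stands for fewer tags in a shallower library, and weaker windows joined to a kept region stay.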

Results

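The study asked how loss of FANCL affects DNA damage in blood cells and during their differentiation. γH2AX regions were called in 8 ChIP-seq libraries of K562 cells, 2 each of WT mock, WT PMA, KO mock and KO PMA. Depth was 23.4 and 23.9 M (mega) tags in WT mock, 17 and 27.2 M in WT PMA, 15.6 and 17.8 M in KO mock, and 16 and 18.3 M in KO PMA. The KO libraries were the shallower ones in mean depth, at 0.749-fold of WT (exact permutation p = 0.111). The lists held from 11959 regions in WT mock replicate 2 to 42896 in KO PMA replicate 1. Between 1.39% (95% Clopper-Pearson interval 1.39 to 1.40%) and 7.96% (7.94 to 7.97%) of a library's tags lay inside its regions. The labels do not say that replicates came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

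In the regions as the authors called them, γH2AX covered the least of the genome in WT mock cells, more in KO mock cells and the most in KO cells treated with PMA. Covered length was 9.14 ± 1.01 Mb in WT mock, 17.6 ± 0.0835 Mb in KO mock, 28.2 ± 4.64 Mb in WT PMA and 38.6 ± 5.69 Mb in KO PMA (mean ± SD, n = 2 each). The share of tags inside regions rose in the same order, at 1.47% ± 0.114, 3.54% ± 0.176, 4.47% ± 0.319 and 7.32% ± 0.892. The file headers give this same share as the approximate efficiency of the immunoprecipitation. It therefore cannot tell more γH2AX from a more efficient immunoprecipitation, and covered length was not corrected for that either. Across both treatments KO libraries were 1.63-fold higher in covered length than WT libraries, and across both genotypes PMA libraries were 2.59-fold higher than mock libraries. Each effect had an exact permutation p of 0.0556, the smallest that these labellings allow. The genotype effect depended on the strength of the regions: at 6-fold over input or more it reversed, from 0.70 to −0.11 on the log2 scale, and WT PMA covered more than KO PMA (−0.50 for KO against WT), while it was 1.89 with one tag threshold and 1.18 with regions of at least 1000 bp.

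**Figure D1:**
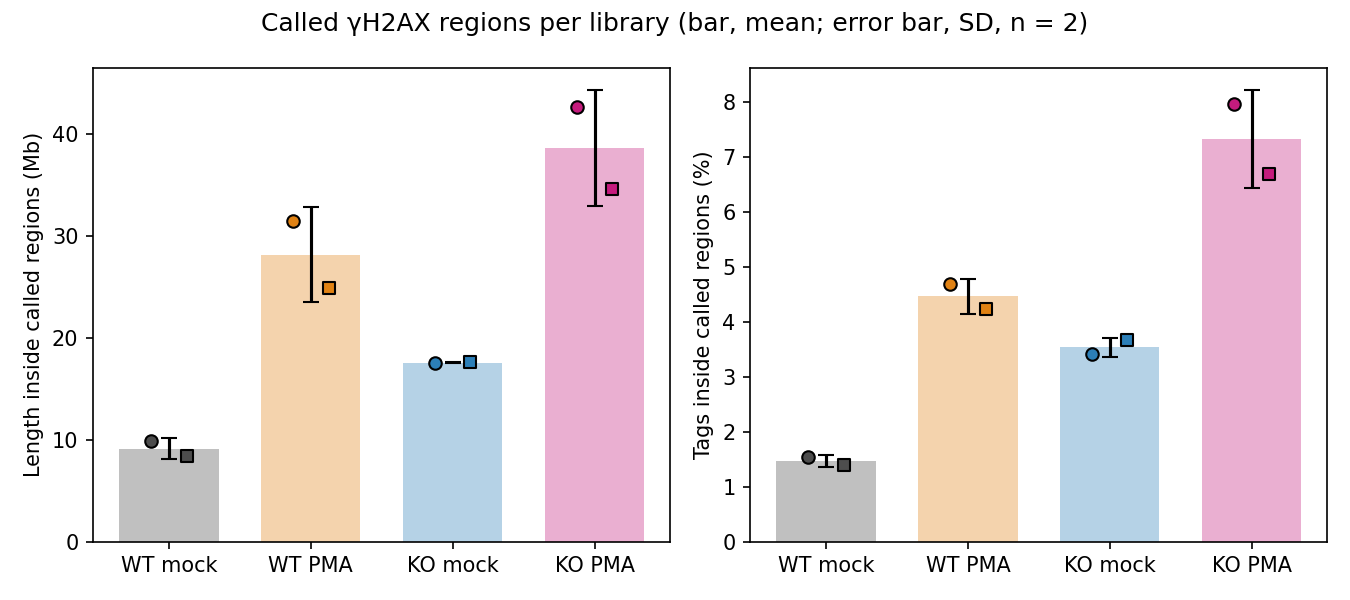
Length inside called γH2AX regions (left, Mb) and share of the library's tags inside them (right, %) for WT mock, WT PMA, KO mock and KO PMA. Points are the 2 libraries of a group, bars their mean and error bars the SD; covered length ranges from 8.42 Mb in a WT mock library to 42.6 Mb in a KO PMA library.

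Replicates of a group shared more of their covered positions than libraries of different groups that differed in genotype. The Jaccard index over base pairs was 0.131 to 0.265 between replicates, 0.0465 to 0.132 between treatments of one genotype, 0.0284 to 0.0677 between genotypes under one treatment, and 0.0239 to 0.0510 where both differed. Regions called in both replicates numbered 2590 in WT mock, 11287 in WT PMA, 7340 in KO mock and 16605 in KO PMA. These were 18.1%, 26.5%, 29.6% and 38.7% of the regions of replicate 1, so most of its regions were not called again. By number of regions, mock replicate 1 overlapped PMA replicate 1 of its genotype (29.2% in WT, 42.3% in KO) more than its own replicate. In the other direction, PMA replicate 1 overlapped mock replicate 1 less than its own replicate, at 9.47% in WT and 21.4% in KO. Regions called in both replicates were ranked by the lower of their 2 folds over input. The first in WT mock lay at the end of chromosome X, from 155238169 to 155238985 (46.6-fold in replicate 1 and 44.5-fold in replicate 2). In WT PMA it lay on chromosome 20 from 46277319 to 46277999 (38.3- and 35.1-fold). In KO mock it lay on chromosome 2 from 166789892 to 166790392 (31.3- and 38.1-fold), and in KO PMA on chromosome 15 from 41770784 to 41771486 (36.7- and 37.2-fold).

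In mock-treated cells, some chromosomes held a larger share of the covered length in KO libraries, and covered length was lower within 200 kb of chromosome ends as defined here. Chromosome 19 held 11.3% ± 0.667 of the covered length in KO and 1.88% ± 0.778 in WT, a 6.25-fold larger share (n = 2 each). Chromosome 16 rose from 3.06% ± 0.773 to 8.74% ± 0.284, chromosome 22 from 1.99% ± 0.286 to 5.55% ± 0.229 and chromosome 17 from 4.68% ± 0.888 to 7.0% ± 0.112. Chromosome 18 fell from 4.01% ± 0.474 to 0.949% ± 0.103 and chromosome 3 from 7.16% ± 0.882 to 2.18% ± 0.0336. In limma on log2 shares, the difference was 2.64 (SE 0.28, adjusted p = 1.67e-05) for chromosome 19, 1.54 (SE 0.15, adjusted p = 1.51e-05) for chromosome 16, and −2.08 (SE 0.15, adjusted p = 1.81e-06) for chromosome 18. Of 23 chromosomes, 10 gained and 10 lost share, a split that a fixed total favours, and in covered length rather than share 15 rose and 2 fell; the share of chromosome 20 did not pass (−0.04, SE 0.13). With one tag threshold for all libraries, chromosome 19 differed by 3.17, while the call for chromosome 22 ended at 0.36. Chromosome X rose from 0.172% ± 0.0119 to 0.327% ± 0.0524 (0.92, SE 0.15, adjusted p = 0.000222), which turned to −0.73 with regions of at least 1000 bp.

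**Figure D2:**
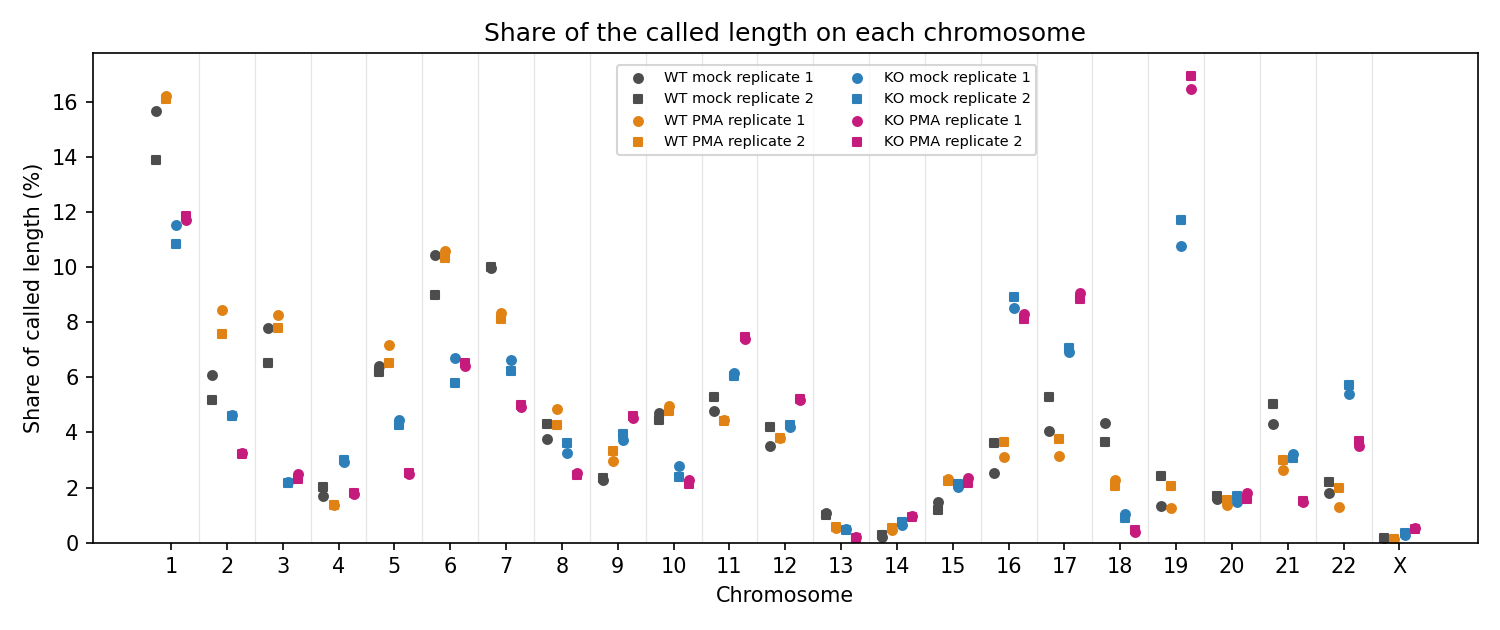
Share of the covered length (%) on each chromosome, from 1 to 22 and X, in each of the 8 libraries; colours mark the group and symbols the replicate. On chromosome 19 the KO libraries lie between 10.8 and 16.9% and the WT libraries between 1.25 and 2.43%.

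Within chromosomes, 1647 bins of 100 kb were higher and 345 lower in KO than in WT mock cells, of 9552 tested in limma. On chromosome 2 the bin from 3400001 to 3500000 held 44.1 ± 4.11 kb of γH2AX in KO and 1.0 ± 0.707 kb in WT. The bin from 1400001 to 1500000 on chromosome 19 held 24.7 ± 2.16 kb against 0.25 ± 0.354 kb, and that from 2200001 to 2300000 on chromosome 16 held 24.3 ± 7.39 kb against 0.5 ± 0.707 kb. Among the lowered bins, that from 100001 to 200000 on chromosome 3 held 42.2 ± 1.05 kb in WT and was listed at 0 in both KO libraries. The bin from 134900001 to 135000000 on chromosome 11 fell from 37.5 ± 0.723 to 0.25 ± 0.354 kb, and the first 100 kb of chromosome 2 from 46.1 ± 6.24 to 0.75 ± 0.354 kb. The adjusted p was 0.000845 in limma for the bins named on chromosomes 2 (from 3400001), 3, 11 and 19. The median bin was 0.29 higher on the log2 scale, and the split was 1184 higher and 567 lower after centring each library, 680 and 623 with the same number of regions from each library, and 2141 and 88 with one tag threshold. The number of changed bins fell to 1008 or 1288 without WT mock replicate 1 or 2, to 899 or 792 without KO mock replicate 1 or 2, and to 250 with regions of at least 6-fold over input, which turned the chromosome 11 bin to 0.29 and ended the call for each other bin named here except that on chromosome 3.

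Lowered bins lay near chromosome ends more often than tested bins did. Of the 345 bins lower in KO mock cells, 36.2% lay within 1 Mb of an end, against 3.80% of the tested bins (permutation p = 0.002 over circular shifts of the bins, the smallest possible). Only bins with called length in WT mock can be lowered, and 38.6% ± 5.15 of the WT mock covered length lay in these windows. The shifts do not account for this, so they do not show that loss favoured the ends over other WT mock regions. Covered length in these windows was 3.41 ± 0.0649 Mb in WT mock and 1.93 ± 0.116 Mb in KO mock, but within 2 Mb the groups overlapped, at 3.61 and 3.78 Mb in WT mock and 3.40 and 3.85 Mb in KO mock. At the start of chromosome 3 it was 101 ± 4.93 kb in WT and 0.25 ± 0.354 kb in KO, at the start of chromosome 2 137 ± 17.3 and 8.57 ± 1.06 kb, and at the end of chromosome 7 413 ± 11.1 and 137 ± 7.5 kb. Both KO libraries lay below both WT libraries at 28 of 41 ends and above them at 7, where chance gives 16.7% of ends in each direction. Among the ends that were higher, the start of chromosome 16 held 35 ± 10.6 kb in WT and 154 ± 19.2 kb in KO, and that of chromosome 19 21.5 ± 6.30 and 82.6 ± 16.7 kb. With one tag threshold for all libraries the windows of 1 Mb no longer separated the groups, at 1.53 and 1.95 Mb in WT mock and 1.49 and 2.01 Mb in KO mock, while within 200 kb of the ends WT mock held 0.815 and 0.903 Mb and KO mock 0.20 and 0.251 Mb.

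**Figure D3:**
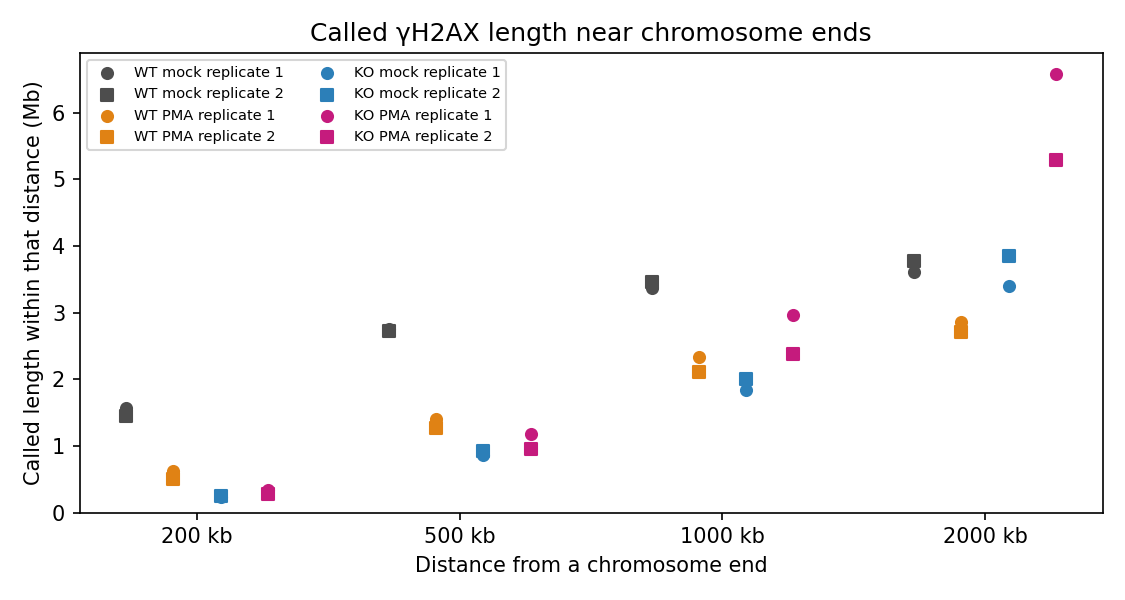
Covered length (Mb, vertical axis) within 200, 500, 1000 and 2000 kb of a chromosome end (horizontal axis) in each of the 8 libraries; colours mark the group and symbols the replicate. Within 1000 kb the WT mock libraries hold 3.37 and 3.46 Mb and the other 6 libraries between 1.85 and 2.97 Mb.

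After PMA, chromosome 19 again held a far larger share of the covered length in KO than in WT libraries. Extra copies of chromosome 19 in KO cells and GC bias of the KO libraries stay open as causes. The share of chromosome 19 was 16.7% ± 0.335 in KO PMA and 1.66% ± 0.578 in WT PMA, 10.4-fold larger (log2 3.38, SE 0.28, limma adjusted p = 1.63e-06, n = 2 each). At 6-fold over input or more the shares were 9.95% and 1.97% (log2 2.36), and with one tag threshold 18.3% and 1.19% (log2 4.12). Chromosome 17 held 8.96% ± 0.160 against 3.45% ± 0.426 and chromosome 16 8.22% ± 0.120 against 3.39% ± 0.377. Chromosome 18 held 0.425% ± 0.0603 against 2.16% ± 0.141 (log2 −2.35, SE 0.15, limma adjusted p = 3.97e-07), and chromosome 3 2.40% ± 0.135 against 8.04% ± 0.334. Chromosome 22 held 3.58% ± 0.131 against 1.64% ± 0.506, a call that ended with one tag threshold (log2 0.13). Chromosome X held 0.508% ± 0.0282 against 0.123% ± 0.00777 (log2 2.05, SE 0.15, limma adjusted p = 7.49e-07). Covered length was 1.37-fold higher in KO PMA than in WT PMA, with the lower KO library at 34.6 Mb and the higher WT library at 31.5 Mb (exact permutation p = 0.33, the smallest possible). The number of regions was 40394.5 ± 3538 in KO PMA and 39399 ± 4451 in WT PMA, a log2 ratio of 0.038 that became 1.12 with one tag threshold, 0.87 with regions of at least 1000 bp, −0.078 without WT PMA replicate 2 and −0.052 without KO PMA replicate 1. With only regions of at least 6-fold over input the number and the covered length reversed, to −0.55 and −0.50.

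**Figure D4:**
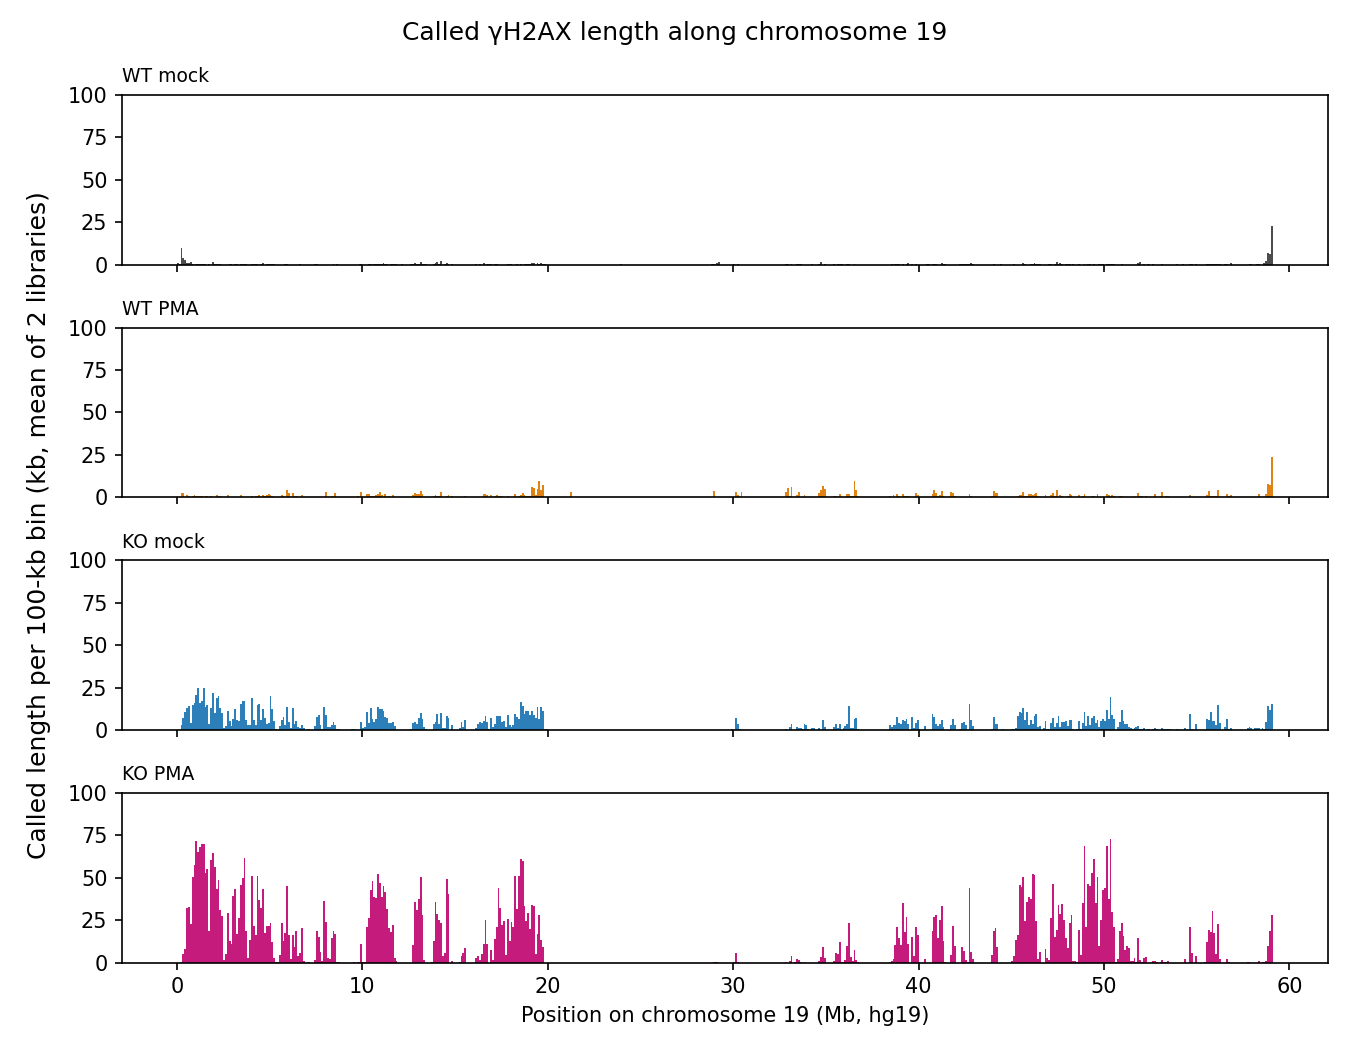
Covered length per 100-kb bin (kb, mean of 2 libraries, vertical axis) along chromosome 19 (Mb, hg19, horizontal axis) in WT mock, WT PMA, KO mock and KO PMA, from top to bottom. The bin from 1400001 reaches 69.9 kb in KO PMA, 24.7 kb in KO mock and 0.25 kb in each WT group.

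Single bins held almost no γH2AX in WT PMA cells and long stretches of it in KO PMA cells, and others the opposite way. The bin from 1400001 to 1500000 on chromosome 19 held 69.9 ± 1.44 kb in KO PMA and 0.25 ± 0.354 kb in WT PMA, and that from 2000001 to 2100000 on chromosome 16 held 61.2 ± 1.07 and 0.638 ± 0.902 kb. On chromosome 9 from 139800001 to 139900000 and on chromosome 11 from 67200001 to 67300000, KO PMA held 59.5 ± 0.00495 and 43.0 ± 6.44 kb, and both WT PMA libraries were listed at 0. On chromosome 3 the bins from 4600001 to 4700000 and from 33900001 to 34000000 held 43.8 ± 3.65 and 24.3 ± 2.49 kb in WT PMA, and 0.828 ± 1.17 and 0.25 ± 0.354 kb in KO PMA. In all, 1517 bins were higher and 2096 lower in KO, with a median difference of −0.21 on the log2 scale. This split depended on the scaling: it was 2114 higher and 1267 lower after centring, 842 and 927 with the same number of regions from each library, and 1582 and 609 with one tag threshold. Without WT PMA replicate 1 there were 1038 higher and 795 lower bins, and without KO PMA replicate 1 the number of changed bins fell from 3613 to 2058. The call ended for the bins named on chromosomes 9 and 11 with regions of at least 6-fold over input.

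The bins that differed between genotypes overlapped between treatments. Of the bins higher in KO, 854 were shared between mock and PMA, where independent lists of these sizes would share 262, and of the bins lower in KO 189 were shared, against 75.7. Opposite calls were rarer than in independent lists: 51 bins were higher under mock and lower under PMA, against 361, and 6 were lower and then higher, against 54.8. The pair of comparisons shares no library.

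In WT cells, covered length was larger at many chromosomal sites after PMA and smaller at 28 of 41 chromosome ends. A more efficient immunoprecipitation could also raise covered length. Covered length rose 3.07-fold, from 9.14 ± 1.01 to 28.2 ± 4.64 Mb (n = 2 each, exact permutation p = 0.33, the smallest possible). On chromosome 1 the bin from 55600001 to 55700000 rose from 0 in both mock libraries to 23.7 ± 6.36 kb. The bin from 154100001 to 154200000 on chromosome 5 rose from 0.138 ± 0.195 to 22.1 ± 0.928 kb, and that from 3100001 to 3200000 on chromosome 10 from 0 in both libraries to 17.3 ± 0.0375 kb. At chromosome ends, the bin from 100001 to 200000 on chromosome 3 fell from 42.2 ± 1.05 to 0.5 ± 0.707 kb, that from 134800001 to 134900000 on chromosome 11 from 30.3 ± 4.34 kb to 0 in both PMA libraries, and that from 100001 to 200000 on chromosome 4 from 18.6 ± 2.86 kb to 0 in both. The adjusted p of these bins lay between 0.000849 and 0.000871 in limma.

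Of the 9552 bins, 3062 were higher and 221 lower after PMA in WT cells. Bins within 1 Mb of a chromosome end made up 52.9% of the lowered and 1.53% of the raised bins, against 3.80% of those tested (permutation p = 0.002 over circular shifts of the bins for each, the smallest possible). Here too 38.6% of the WT mock covered length lay in these windows. For the lowered bins the shifts therefore do not show that loss favoured the ends over other WT mock regions. Covered length in these windows fell from 3.41 ± 0.0649 to 2.22 ± 0.158 Mb, and with one tag threshold it was 1.53 and 1.95 Mb in mock and 0.947 and 1.31 Mb in PMA libraries. Both PMA libraries lay below both mock libraries at 28 of 41 ends and above them at 9, where chance gives 16.7% of ends in each direction. The end of chromosome 15 rose, from 44.3 ± 9.25 to 79.3 ± 14.5 kb. This comparison and that of the genotypes under mock share the WT mock libraries, so the pair of lowered sets at the ends is not independent. Chromosome 14 rose from 0.241% ± 0.0350 to 0.498% ± 0.0534 of the covered length and chromosome 15 from 1.33% ± 0.218 to 2.27% ± 0.0349. Chromosomes 13 and 21 fell in share, from 1.05% ± 0.0589 to 0.557% ± 0.0220 and from 4.68% ± 0.510 to 2.82% ± 0.250. Each of these 4 shares had a limma adjusted p of 0.000919. In covered length rather than share, all 23 chromosomes rose, chromosome 13 by 0.74 and chromosome 21 by 0.92 on the log2 scale, and the call for the share of chromosome 13 ended at 6-fold (−0.21). The median bin was 0.66 higher, and the split was 1247 higher and 941 lower after centring, 510 and 445 with the same number of regions from each library, and 876 and 54 with one tag threshold. The number of changed bins fell from 3283 to 1432 without WT PMA replicate 1 and to 1623 without WT mock replicate 2. With regions of at least 6-fold over input the call ended for the bins named on chromosomes 1 and 5.

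In KO cells, the covered length was also larger after PMA, partly as long regions. As above, more γH2AX cannot be told from a more efficient immunoprecipitation. Covered length rose 2.18-fold, from 17.6 ± 0.0835 to 38.6 ± 5.69 Mb (n = 2 each, exact permutation p = 0.33, the smallest possible). Regions of at least 5 kb numbered 42 and 47 in KO mock and 667 and 394 in KO PMA. In the other groups there were 66 in each WT mock library and 85 and 43 in WT PMA. Chromosome 19 held 30.1 and 32.2% of these long regions in KO PMA. The longest in KO PMA replicate 1 spanned 26470 bp on chromosome 11, from 65155479 to 65181949, at 3.58-fold over input. No region of this length was left in KO PMA when only regions of at least 6-fold over input were kept.

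On chromosome 14 the bin from 23400001 to 23500000 rose from 0.574 ± 0.811 kb in KO mock to 20.3 ± 0.545 kb in KO PMA (limma adjusted p = 0.00408), and on chromosome 22 the bin from 26900001 to 27000000 rose from 0 in both libraries to 9.60 ± 0.184 kb (adjusted p = 0.00435). On chromosome 5 the bin from 1600001 to 1700000 fell from 10.5 ± 1.34 to 0.25 ± 0.354 kb, and on chromosome 2 the bin from 3100001 to 3200000 from 19.2 ± 0.390 to 2.07 ± 0.607 kb. With regions of at least 6-fold over input the call ended for each of these 4 bins, and with a pseudocount of 100 bp for that on chromosome 2 (adjusted p = 0.0897). Chromosome 13 fell from 0.486% ± 0.0181 to 0.180% ± 0.0364 of the covered length, chromosome 18 from 0.949% ± 0.103 to 0.425% ± 0.0603 and chromosome 21 from 3.13% ± 0.102 to 1.49% ± 0.0212. In covered length, chromosomes 13, 18 and 21 differed by −0.29, −0.01 and 0.08 on the log2 scale and did not pass; the call for the share of chromosome 13 also ended at 6-fold (−0.38). The larger share of chromosome 19 after PMA did not pass either (log2 0.57, SE 0.28, limma adjusted p = 0.0896). It passed with regions of at least 1000 bp (0.75, limma adjusted p = 0.0256) and with the replicate number as a block (limma adjusted p = 0.00331). The difference stayed at 0.57 without WT PMA replicate 1 or 2 and was −0.0053 at 6-fold. Near chromosome ends, covered length was 1.93 ± 0.116 Mb in KO mock and 2.67 ± 0.420 Mb in KO PMA, and with one tag threshold the groups overlapped, at 1.49 and 2.01 Mb in KO mock and 2.17 and 2.0 Mb in KO PMA. Both KO PMA libraries lay above both KO mock libraries at 16 of 41 ends and below them at 16, and 9.02% of the lowered bins lay within 1 Mb of an end, against 3.80% of those tested (permutation p = 0.004 over circular shifts of the bins). In KO mock 11.2% ± 0.628 of the covered length lay in these windows, so this p does not show that loss favoured the ends. In all, 1252 bins were higher and 510 lower after PMA, with a median difference of 0.21 on the log2 scale; the split was 1455 and 395 after centring, 291 and 260 with the same number of regions from each library, and 845 and 671 with one tag threshold. Leaving out KO mock replicate 1 or 2 lowered the number of changed bins from 1762 to 513 or 524, and leaving out KO PMA replicate 1 or 2 lowered it to 537 or 835.

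The response to PMA differed between the genotypes at 1571 bins by the interaction term in limma. Most of them, 1209, gained less or lost more covered length in KO than in WT, a direction that centring each library turned to 812 positive and 195 negative. On chromosome 1 the bin from 55600001 to 55700000 was listed at 0 in both mock groups and held 23.7 ± 6.36 kb in WT PMA but 0.25 ± 0.354 kb in KO PMA. On chromosome 2 the bin from 9000001 to 9100000 rose from 0.25 ± 0.354 to 14.2 ± 0.441 kb in WT and held 1.0 ± 0.707 and 0.25 ± 0.354 kb in KO (log2 −4.29, SE 0.53, limma adjusted p = 0.00781). The interaction call ended for both bins with regions of at least 6-fold over input. At the other 362 bins the difference was positive. Among them were the ends of chromosome 11 and chromosome 3 that lost covered length with PMA in WT. These held almost none in KO mock cells, so little could be lost there in KO. A pseudocount of 100 bp ended the call for the bins from 9000001 on chromosome 2 (adjusted p = 0.0503) and from 100001 on chromosome 3 (adjusted p = 0.0536).

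Of the bins raised by PMA, 581 were shared between the genotypes, against 401 for independent lists, and of the lowered bins 53 were shared, against 11.8. Opposite calls numbered 26 for higher in WT and lower in KO, against 163, and 9 for the reverse, against 29.0. These lists also share the estimate of the spread and the input, so independent lists are no full expectation. The number of regions of at least 5 kb rose with PMA in KO relative to WT, by 3.65 on the log2 scale (exact permutation p = 0.0556, the smallest possible). Covered length within 1 Mb of the ends also differed in its response, by 1.09 (exact permutation p = 0.0556), and total covered length by −0.49 (exact permutation p = 0.444), which turned to 0.19 with regions of at least 1000 bp. The permutation p-values given here shuffled genotype within each treatment, so they do not test equal responses to PMA alone. The median bin was lower by 0.54 in the interaction, and centring turned its split to 812 positive and 195 negative. The split was 434 and 406 with the same number of regions from each library and 293 and 737 with one tag threshold. Without replicate 1 or 2, the number of bins was 891 or 695 for WT mock, 486 or 941 for WT PMA, 558 or 571 for KO mock and 770 or 801 for KO PMA.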

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

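The tests of dilution near chromosome ends, of depth for WT mock against WT PMA within 1 Mb and within 200 kb, and both tests of mitochondrial DNA were chosen only after the result was seen, as were the measures they rest on; the depth test for KO mock within 200 kb was added after that within 1 Mb but before its own value was known.

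Bins whose response to PMA differed between WT and KO by the interaction term numbered 1571, which singled out this set for a closer look. The unplaced contig GL000220.1 and the decoy sequence lie outside the chromosomes compared, and held 41.6 and 177.9 kb of called length in KO mock, against 21.9 and 80.2 kb in WT mock.

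Covered length within 1 Mb of chromosome ends was highest in WT mock. Its response to PMA differed by 1.09 on the log2 scale between KO and WT (exact permutation p = 0.0556 with genotype shuffled within each treatment, the smallest possible). If one tag threshold removed the effect of depth, different depths would predict no gap under it. Within 200 kb of the ends the lower WT mock library still exceeded the higher KO mock library 3.24-fold and the higher WT PMA library 2.35-fold. The threshold does not remove depth in full, since weaker windows joined to a kept region stay. At its own threshold the deepest library, WT PMA replicate 1, held 0.628 Mb there against 1.46 Mb in the lower WT mock library. These values argue against depth as the whole cause within 200 kb. Within 1 Mb different sequencing depth stays open. The ratio of the lower WT mock library to the highest other library was 0.7, as depth predicts, but a shallower library passes the threshold with fewer tags, which can itself lower this ratio. The ratio to the higher WT PMA library was 1.17, a gap smaller than the larger SD, a criterion set after seeing it. At its own threshold, however, WT PMA replicate 1, at 27.2 M tags, held 2.33 Mb against 3.37 Mb in the lower WT mock library. Dilution by regions called elsewhere lowers a share. A lower share alone does not alter a covered length, such as the 2.32-fold excess of the lower WT mock library over the highest other library within 200 kb. That value was known beforehand and restates the pattern, so it tests nothing. Windows are called against a fixed depth, so tags drawn to other regions could lower those at the ends. Between 1.39% and 1.55% of tags lay inside regions in WT mock, and at most 7.96% in any library. Regions called elsewhere could thus draw few tags from the ends, which argues against this as the whole cause of that excess. Tags gathered outside called regions were not counted, so that part stays open. A candidate explanation with no test of its own is that FANCL loss and, in WT cells, PMA lower γH2AX close to the ends. In KO cells covered length within 200 kb was not lower after PMA, at 0.241 and 0.251 Mb in KO mock and 0.345 and 0.284 Mb in KO PMA.

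Mitochondrial DNA was called over most of its length in both KO PMA libraries, at 3.29-fold over input in replicate 1 and 3.39-fold in replicate 2; in the other 6 libraries the call was absent apart from a region of 500 bp in WT PMA replicate 2, at 2.1-fold. Greater depth would need these 2 libraries to be deeper than those without the call, whereas the shallower of them lay below the deepest library without it (difference −11.2 M tags). A larger amount of mitochondrial DNA in these libraries stays open as a cause. The 99.4% of the molecule called in the library with less restates the pattern and decides nothing. No biological explanation was tested.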

How the results depend on the processing

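The alternatives with one tag threshold for all libraries, regions of at least 1000 bp, the bound on the residual spread, other end windows, and all alternatives for chromosome shares were chosen only after seeing the data. Where a value moved, the cause was not tested, except that fewer regions or larger bins leave fewer bins to test. Tests of genes, gene lists and windows around transcription starts under other settings, fixed beforehand, were not run, for lack of an hg19 annotation. The setting with no filter was run on bins covered in at least 1 library, since bins at 0 throughout have no spread and gave false calls.

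The log2 ratio of covered length was positive under all alternatives run for KO against WT under mock, PMA in WT and PMA in KO. With regions of at least 6-fold over input it was 0.29 for KO against WT under mock and 0.83 for PMA in KO, reversed to −0.50 for KO against WT under PMA, and was −0.80 for the interaction. With one tag threshold these were 2.29, 0.85, 1.49 and −0.80. With regions of at least 1000 bp PMA in KO gave 1.89, KO against WT under PMA 1.27, and the interaction reversed to 0.19. KO against WT over both treatments reversed to −0.11 at 6-fold, and was 1.89 with one tag threshold and 1.18 with regions of at least 1000 bp, which gave 1.80 for PMA over both genotypes; leaving out 1 library gave 0.62 to 0.79 and 1.29 to 1.46. For the number of regions, 6-fold gave 0.32 for KO against WT under mock and reversed KO against WT under PMA to −0.55. One tag threshold gave 2.61 and 1.12 for these, 1.79 for PMA in WT, 0.30 for PMA in KO and −1.49 for the interaction. Regions of at least 1000 bp gave 1.37, 0.87, 2.02, 1.52 and −0.50 in the same order. Leaving out 1 library gave −0.078 to 0.15 for the number of regions in KO against WT under PMA, reversed to −0.078 without WT PMA replicate 2 and to −0.052 without KO PMA replicate 1.

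Counts of changed bins are given in the order KO against WT under mock, KO against WT under PMA, PMA in WT, PMA in KO, and interaction. They were 250, 1230, 1138, 369 and 727 with regions of at least 6-fold, 1303, 1769, 955, 551 and 840 with the same number of regions from each library, and 687, 1064, 1303, 442 and 578 with bins of 1 Mb. Regions of at least 1000 bp gave 613, 1950, 1033 and 1081 for the first 4. One tag threshold gave 2191 for KO against WT under PMA, 930 for PMA in WT and 1030 for the interaction. Centring gave 2188 for PMA in WT and 1007 for the interaction, a pseudocount of 100 bp gave 2289 for KO against WT under PMA, and the filter of 4 libraries gave 747 for the interaction. Leaving out 1 library gave 792 to 1998, 1833 to 3315, 1432 to 2994, 513 to 1797 and 486 to 941; the group with 1 library left is then assumed to vary like the others. Counts under the other settings stayed within 1.5 times the reported ones.

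The replicate numbers were tested as a block. Deviations of same-numbered libraries correlated at −0.0585 to 0.164 over the 6 pairs of groups, so with 2 numbers the libraries share only a number. With the block there were 1756, 3423, 3114, 1521 and 1108 changed bins, and changed chromosome shares numbered 20, 21, 11, 16 and 10. Chromosome 19 for PMA in KO passed with the block (adjusted p = 0.00331), and the bin from 155000001 on chromosome 1 did not in the interaction (adjusted p = 0.0512). The ratios of whole libraries do not change by construction. With 2 pairs the smallest paired permutation p is 0.5.

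Chromosome shares changed at 20, 21, 11, 15 and 8 of 23 chromosomes. Covered length in place of the share gave 23 for PMA in WT and 13 for the interaction, with 15 higher and 2 lower for KO against WT under mock, and 11 and 7 under PMA; the chromosomes that passed for PMA in WT and in KO were higher, and those for the interaction negative. Regions of at least 1000 bp gave 18 for PMA in WT, one tag threshold 8 for PMA in KO and 4 for the interaction, and 6-fold 15 for the interaction. Leaving out 1 library gave 8 to 16 for PMA in KO and 3 to 12 for the interaction. Chromosomes 3, 4, 11, 13 to 19, 21, 22 and X, chosen after their values were seen, were followed in the first 4 comparisons, whether or not they passed.

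Covered length in place of the share reversed, for PMA in WT, chromosomes 4 (1.21), 11 (1.47), 13 (0.74), 17 (1.22), 18 (0.76), 19 (1.49), 21 (0.92), 22 (1.34) and X (1.17), and for PMA in KO, chromosomes 4 (0.43), 16 (1.06), 21 (0.079) and 22 (0.52), since total length rose. For KO against WT it reversed chromosome 21 under mock (0.38) and chromosome 15 under PMA (0.44). Regions of at least 6-fold reversed chromosomes 3 (−0.14), 4 (0.12) and 11 (0.029) for PMA in WT, 19 (−0.0053) and 22 (0.44) for PMA in KO, and 15 (0.27) for KO against WT under PMA. One tag threshold reversed chromosome 15 for KO against WT under PMA (0.59), and chromosomes 3 (−0.030) and 15 (−0.076) for PMA in KO. Regions of at least 1000 bp reversed chromosome X for KO against WT under mock (−0.73), 15 for KO against WT under PMA (0.12) and 22 for PMA in WT (1.31). Leaving out 1 library turned the direction of chromosome 15 for KO against WT under PMA (−0.077 to 0.046), and, for PMA in WT, of chromosomes 16 (−0.095 to 0.43), 19 (−0.60 to 0.27) and 22 (−0.63 to 0.010). For PMA in KO the calls for chromosomes 11 (0.27 to 0.29), 14 (0.34 to 0.53) and 17 (0.34 to 0.37) ended without any one of the KO libraries, and that for 22 (−0.67 to −0.59) without any but KO PMA replicate 2, while chromosome 19 passed without WT PMA replicate 1 or 2. For PMA in WT the call for chromosome 17 ended without WT mock replicate 2 (−0.23) or WT PMA replicate 1 (−0.30), and that for X without WT mock replicate 2 (−0.41) or WT PMA replicate 1 (−0.42) or 2 (−0.55). Chromosomes 3 (0.30) and 11 (−0.26) passed there without WT mock replicate 1, 16 (0.43) without WT mock replicate 2 and 22 (−0.63) without WT PMA replicate 2. For KO against WT under PMA the call for chromosome 4 ended without KO PMA replicate 2 (0.36). The share of chromosome 19 was 9.96% in KO mock and 9.95% in KO PMA at 6-fold, and 18.3% in KO PMA with one tag threshold.

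The share within 1 Mb of chromosome ends, in the order WT mock, WT PMA, KO mock and KO PMA, was 28.2%, 5.59%, 9.06% and 4.98% at 6-fold. One tag threshold gave 58.7%, 11.5% and, in KO PMA, 7.63%. Windows of 500 kb gave 31.0%, 4.78%, 5.17% and 2.77%, and windows of 2 Mb 10.0% in WT PMA, 21% in KO mock and 15.4% in KO PMA.

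Reproducible regions at 6-fold numbered 275, 1314, 376 and 931 in the same order. With the same number of regions from each library there were 2555 in WT PMA, 3154 in KO mock and 4123 in KO PMA, and with an overlap of 50% of the region 7046 in WT PMA and 10404 in KO PMA. Regions gained and lost at 6-fold numbered 342 and 252 for KO against WT under mock, 757 and 1114 under PMA, 1176 and 188 for PMA in WT, and 757 and 269 for PMA in KO. With the same number from each library they numbered 2357 gained for KO against WT under mock, 3152 and 1773 under PMA, 1650 gained for PMA in WT, and 1823 and 1236 for PMA in KO.

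Of 50 bins named by rule, 42 of them distinct, 43 kept their call without any one library. A pseudocount of 100 bp ended 8 calls, the same number of regions from each library 3, regions of at least 1000 bp 1 and the replicate block 1. With regions of at least 6-fold 28 lost it and the bin from 134900001 on chromosome 11 reversed to 0.29 for KO against WT under mock.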

Other observations

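The test of base composition on chromosome 19 was chosen only after the result was seen, as was the analysis of contigs and input density; the repeat of the copy number test was added after its first value, with its prediction fixed before the second value was known.

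On 3 unplaced contigs and the decoy sequence, called length was lower after PMA in both genotypes. The contig GL000224.1 held 45.1 ± 11.9 kb of called length in WT mock and 11.8 ± 1.18 kb in WT PMA, and 52.4 ± 0.480 kb in KO mock and 8.80 ± 0.288 kb in KO PMA (n = 2 each). The contig GL000205.1 fell from 20.8 ± 4.04 to 4.14 ± 0.484 kb in WT and from 12.3 ± 0.941 to 1.39 ± 0.362 kb in KO. The contig GL000220.1 fell from 21.9 ± 6.96 to 10.6 ± 1.92 kb in WT and from 41.6 ± 1.83 to 11.4 ± 1.46 kb in KO, and the decoy sequence from 80.2 ± 16.1 to 35 ± 0.115 kb in WT and from 178 ± 12.3 to 54.7 ± 8.19 kb in KO. For each of the 4 the exact permutation p of the PMA effect was 0.0556, the smallest possible. The other 2 sequences examined did not follow. Mitochondrial DNA went from 0 in both KO mock libraries to 16.5 ± 0.0120 kb in KO PMA. The contig GL000195.1 held 28.9 ± 3.60 kb in WT mock and 31.8 ± 9.41 kb in WT PMA; its PMA effect was −0.03 on the log2 scale (exact permutation p = 0.889), and KO libraries held 2.46-fold less of it than WT libraries (exact permutation p = 0.0556).

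Called regions on chromosome 22 held more input than those on other chromosomes, with a median over libraries of 22.8 input tags per kb, against 4.62 on chromosome X and 11 on chromosome 9, the lowest and highest of the others. The longest region of both KO mock libraries lay there, from 23608418 to 23624046 in replicate 1 at 2.09-fold and from 23609980 to 23624197 in replicate 2 at 2.18-fold over input.

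Chromosome 19 held a larger share of the covered length in KO than in WT libraries. The prediction fixed for different sequencing depth was a difference below 1 on the log2 scale under mock once one tag threshold is used, and it was 3.17 (SE 0.42). That threshold does not remove depth in full. In depth, WT PMA replicate 2 (17 M tags) lay between the KO PMA libraries (16 and 18.3 M). Its chromosome 19 share at its own threshold was 2.07%, against 16.9% and 16.5% in these. Both results argue against depth as the whole cause. Extra copies of chromosome 19 in KO cells stay open. The KO mock library with fewer chromosome 19 regions at 6-fold held 458, and the WT mock library with more at 3-fold held 328. Their ratio was 1.4 (SE 0.1, which does not measure the spread between libraries), above the limit of 1 fixed beforehand. That limit was wrong, since WT windows below the tag threshold are missing from the WT list. The test was repeated above thresholds complete in both lists, where WT mock held 31 and 77 regions at 3-fold. The ratio was 0 because no region of any mock library reached 6-fold at double the tag threshold. This makes the test void, under a minimum number of regions set after seeing it. GC bias of the KO libraries stays open too, since base composition was not measured; the lowest difference among the GC-rich chromosomes 16, 17, 19, 20 and 22 was −0.04 (SE 0.13), on chromosome 20. Loss of FANCL itself may cause the shift, as a hypothesis found on these data and not tested apart from these explanations.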
